A study of Macaca fascicularis with 162 samples.

How the data were processed

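The samples were lung slices of 9 cynomolgus macaques (Macaca fascicularis), kept in culture with poly IC, labelled as 100 mg, or with a mock control and taken at 2, 6 and 24 h. Each animal, treatment and time had 3 arrays that the labels call technical replicates, which gave 162 arrays, 27 in each of 6 groups. The arrays carried biotin-labelled RNA and human U133-type probe set names, so each value was the signal of macaque RNA on probes named for human genes. The deposited values are on a log2 scale, and the processing notes of the submitters name RMA (robust multi-array average), which corrects background, normalises between arrays and summarises the probes of a probe set. No version of RMA is given. The values ran from 0.63 to 13.89, the array medians lay between 5.65 and 5.88, and 14694 probe sets were held for each array. The notes used here do not say how these probe sets were chosen.

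For every probe set, the 6 arrays that share an animal and a technical replicate number had the same mean as all arrays. The 27 such sets differed from the mean of the probe set by at most 3.8e-05 log2 units, and all 14694 probe sets met a tolerance of 0.001. The level of each set had therefore been removed before deposition, by a step that the labels do not describe. Levels were not compared between animals for this reason. The planned test of whether arrays of an animal resemble each other more than arrays of other animals was void, because this centring fixes its outcome. No arrays were identical, with 0 such cases, and the highest correlation between any 2 arrays was 0.9935. The lowest correlation between technical replicates was 0.938.

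The technical replicates of an animal, treatment and time were averaged, so that the animal was the unit of replication and 54 values entered the fit for each probe set. Every animal was in all 6 groups, as its labels state, and the animal was a block in the fit. The fit had 6 groups and 9 animals and left 40 residual degrees of freedom. It was made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, prior degrees of freedom 4.06), and p values were adjusted with the Benjamini-Hochberg method over all 14694 probe sets of a comparison. The threshold was an adjusted p of 0.05, with no filter on low signal. The comparisons were poly IC against mock slices at each of the 3 times, the difference between these effects at different times, and mock slices at different times. All limma tests were two-sided. A value in the text is a log2 difference with the SD between the 9 animals, unless it says otherwise.

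Of the 14694 probe sets, 13761 were in the probe table, 933 were not, and 339 had several gene symbols. The 13422 with 1 symbol belonged to 9122 genes, of which 2991 had more than 1 probe set. Of the 9122 symbols, 8683 were also in the macaque gene table. Where a gene had several probe sets, the probe set with the highest mean stood for the gene. Named genes followed a rule: the 10 largest rises and 5 largest falls at each poly IC comparison among genes past the threshold with the same direction in all 9 animals, and the 5 largest of each for the other comparisons. A short list of inflammatory and antiviral genes was given at every time, and the members with the largest difference stood for each gene list, up to 3 of them. Genes of that short list that the text gives no value for were not analysed here.

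Altogether 36 gene lists for interferon and cytokine responses, cell stress, tissue remodelling and cell types of the lung were tested with camera in limma, at a preset correlation of 0.01 between genes and with 1 probe set per gene. The 108 tests of 36 lists at 3 times were adjusted together. Counts of list members refer to the adjustment over all probe sets, and counts adjusted over the list alone are given beside them. The same test with an estimated correlation, and fry, were run as alternatives. For 3 lists, the mean difference over the list was taken for each animal and tested with an exact two-sided sign-flip test over the 9 animals, and the responses at different times were compared with Pearson's r and Spearman's rho, each with an exact permutation test. The groups, comparisons, gene lists, naming rule and main tests were chosen before the data were examined.

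The alternatives that were tried were other uses of the technical replicates, a fit without the animal block, a fit of only the groups compared, other scalings of the arrays, another prior in eBayes, a filter on the dimmest 30% of probe sets, 1 value per gene, stricter thresholds and leaving out each animal. Animal levels had been removed with the set levels, so dropping the block leaves the differences unchanged. It only adds residual degrees of freedom that the centring had used, which makes its p values too small. The list tests on differences between times and on mock slices, the counts without the HLA genes, the fit with 27 set terms, the mean of the probe sets of a gene in the counts, and the fits without animals 1 and 2 were added after the data had been seen.

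The pipeline was tested on simulated data with 14694 probe sets, made from the mock means at each time with independent noise for each probe set. Differences were then added to the poly IC arrays at 2 h. The simulated data held no other signal tied to the arms, so they say nothing about such a signal. Of the probe sets with a simulated difference of 0.25, 61.2% were called (41 of 67), of those with 0.5, 97% (65 of 67), and of those with 1, 100% (66 of 66), with 0 called in the wrong direction. Of 14494 unchanged probe sets, 7 were called. The number of arrays limits the precision: the median SD between technical replicates was 0.17, the median SD of animal means about the fit was 0.12, and the median standard error of a poly IC difference was 0.055.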

Results

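Slices of lung from 9 cynomolgus macaques were kept in culture with poly IC or a mock control. Poly IC is a synthetic double-stranded RNA that cells sense much as they sense viral RNA. RNA was measured on arrays after 2, 6 and 24 h. Slices of every animal were in both arms and at all 3 times, with 3 technical replicate arrays each, so that each of the 6 groups held 27 arrays. Signal was given on a log2 scale for each probe set. The number of arrays limits the precision. Differences are poly IC minus mock, or later minus earlier time, with the SD between the 9 animals.

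The comparison at 2 h asked which transcripts differed between poly IC and mock slices early in culture. AHNAK, a large scaffold protein, had the largest rise, 0.72 ± 0.077 (adjusted p = 5.5e-14). It was followed by the heat shock co-chaperone DNAJA4, 0.69 ± 0.48 (adjusted p = 0.029), and by CHMP4B, a part of the ESCRT-III membrane-remodelling complex, 0.67 ± 0.12 (adjusted p = 1.2e-13). FRAS1, a protein of the epithelial basement membrane, rose by 0.67, the Golgi protein GOLM1 by 0.66, the deubiquitinase OTUD7B by 0.65 and IGFBP7, a secreted binding protein for insulin-like growth factors, by 0.63. The kinase STK16, C1orf115 and the ubiquitin ligase UBR4 rose by 0.62, 0.59 and 0.57. Fibronectin (FN1), a main protein of the extracellular matrix, had the largest fall, −0.85 ± 0.35 (adjusted p = 4.7e-09), followed by IGFBP2 at −0.58 ± 0.24 (adjusted p = 0.013). The replication factor subunit RFC5, the translation initiation factor EIF4G1 and the kinase DCLK1 also fell, to differences of −0.48, −0.38 and −0.37. All of these had the same direction in 9 of 9 animals. With the mean of the probe sets of each gene, AHNAK was at −0.072 (adjusted p = 0.18), since its 3 probe sets gave 0.72, 0.12 and −1.06, and DNAJA4 (0.22; adjusted p = 0.35) and DCLK1 (−0.23; adjusted p = 0.073) did not pass the threshold. The other probe sets of CHMP4B (0.073, adjusted p = 0.49), IGFBP7 (0.15, adjusted p = 0.27) and EIF4G1 (−0.059, adjusted p = 0.4) did not pass either.

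Few antiviral genes had moved at 2 h. Of 37 measured interferon-stimulated genes with antiviral roles, 6 rose and 0 fell (6 and 0 adjusted over the list alone), the median was 0.03, and the list as a whole did not pass (adjusted p = 0.96). PARP14 rose by 0.30 ± 0.16 (adjusted p = 0.00065, 9 of 9 animals) and IFIT3 by 0.29 ± 0.18 (adjusted p = 0.023, 8 of 9). IFIT1 had the largest difference of the list, 0.38 ± 0.26, higher in 9 of 9 animals, but did not pass (adjusted p = 0.068). With all arrays entered singly IFIT1 did pass (adjusted p = 0.015). The p values of that fit can be too small, because it gives all probe sets 1 correlation between technical replicates. IFIT1 also passed without the animal block (adjusted p = 0.037), a fit whose p values are too small because animal levels had already been removed. ISG15, a ubiquitin-like protein that interferon induces strongly, was at −0.0049 (adjusted p = 0.99), and the RNA sensors RIGI and IFIH1 were at 0.0047 and 0.10 (adjusted p = 0.98 and 0.53). The chemokine CCL5, which draws T cells and monocytes, rose by 0.42 ± 0.17 (adjusted p = 0.027, 9 of 9 animals), although with the mean of its 3 probe sets it did not pass (0.27; adjusted p = 0.062). CXCL10 (−0.22), IL6 (−0.25), IL1B (0.15), CXCL8 (0.057) and CD274 (0.095) did not pass, with adjusted p = 0.44, 0.69, 0.46, 0.84 and 0.76. Of 10 inflammatory cytokines, only lymphotoxin beta (LTB) rose, by 0.23 ± 0.11 (adjusted p = 0.0087; 1 adjusted over the list alone).

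The genes of MHC class I presentation, which displays peptides from inside the cell to T cells, formed the only list called at 2 h of the 36 tested (median 0.10, adjusted p = 0.0016, and adjusted p = 1 with an estimated correlation). Of its 17 measured members 8 rose and 0 fell (9 and 1 adjusted over the list alone). NLRC5, the activator of class I transcription, rose by 0.37 ± 0.16, HLA-F by 0.34 ± 0.19 and HLA-G by 0.28 ± 0.12. Leaving out animal 1 gave 3 called lists and leaving out animal 9 gave 2. The 5 HLA genes, whose sequences are alike, all rose (median 0.27), and of the other 12 members 3 rose (median 0.085). The HLA median was 0.29 at both 6 and 24 h, so it hardly changed with time, like the calls shared by the 3 times that are described below. Whether it has the same cause as those calls was not tested. Of 13 fibroblast and matrix markers, FN1 and the microfibril protein MFAP5 (−0.34 ± 0.39, adjusted p = 0.025) fell and 0 rose (2 and 0 adjusted over the list alone; list adjusted p = 0.15). Altogether 3162 probe sets (21.5%) differed at 2 h, 2104 higher and 1058 lower, with a median absolute difference of 0.20, and 3 differed by 2-fold or more. The share that was higher, 66.5%, was 48.7% once the median of each array had been subtracted.

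At 6 h several antiviral genes were among the 10 largest rises. IFIT2 and IFIT3, antiviral genes of the IFIT family, rose by 1.24 ± 0.60 (2.36-fold; adjusted p = 1.3e-07) and 0.87 ± 0.32 (adjusted p = 3.3e-09), each in 9 of 9 animals. The antiviral scramblase PLSCR1 rose by 0.60 ± 0.36 (adjusted p = 0.00015), IFI44 by 0.59 ± 0.24 (adjusted p = 0.00064) and PMAIP1 (NOXA), which promotes cell death, by 0.58 ± 0.32 (adjusted p = 0.00031). AHNAK (0.70), CHMP4B (0.65), IGFBP7 (0.61), UBR4 (0.59) and the splicing factor HNRNPH1 (0.60) made up the rest of the 10 largest rises. The largest falls were those of FN1, −0.90 ± 0.18 (adjusted p = 1.5e-09), IGFBP2, −0.65 ± 0.31, the kinase WNK3, −0.60 ± 0.27, EIF4G1, −0.53 ± 0.13, and LMO7, −0.49 ± 0.19. With the mean of the probe sets of each gene, AHNAK was at −0.098 (adjusted p = 0.055) and LMO7 at −0.18 (adjusted p = 0.073). The other probe sets of CHMP4B (0.044, adjusted p = 0.7) and EIF4G1 (−0.073, adjusted p = 0.28) did not pass, and that of IGFBP7 was at 0.26 (adjusted p = 0.037).

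Of the 37 antiviral interferon-stimulated genes, 16 rose and 0 fell at 6 h (16 and 0 adjusted over the list alone, median 0.11). The list passed at the preset correlation (adjusted p = 4.4e-05) and did not with an estimated correlation (adjusted p = 1 with an estimated correlation). ISG15 rose by 0.60 ± 0.58 (adjusted p = 0.0016, 8 of 9 animals) and IFIT1 by 0.57 ± 0.37 (adjusted p = 0.0052, 9 of 9). Among 18 genes of double-stranded RNA sensing and interferon signalling, 4 rose and 1 fell (4 and 1 adjusted over the list alone; list adjusted p = 0.46). They included the sensors RIGI, 0.51 ± 0.28 (adjusted p = 1.6e-05), and IFIH1, 0.44 ± 0.23 (adjusted p = 0.0011), and the transcription factor IRF1, 0.42 ± 0.46 (adjusted p = 0.010). In the MHC class I list, 8 of 17 members rose and 1 fell (8 and 1 adjusted over the list alone, median 0.15, adjusted p = 0.0011, and adjusted p = 1 with an estimated correlation). HLA-G, HLA-F and HLA-C rose by 0.33, 0.31 and 0.29, and of the 12 members outside the 5 HLA genes 3 rose and 1 fell (median 0.081).

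Inflammatory genes showed a wide spread between animals at 6 h. Of 17 target and feedback genes of NF-kB, the transcription factor behind many inflammatory genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.26), and the list did not pass (adjusted p = 0.15). The adhesion molecule VCAM1 rose by 0.66 ± 0.83 (adjusted p = 0.038, 7 of 9 animals), while PTGS2, 0.68 ± 1.4, and SELE, 0.49 ± 0.94, did not pass (adjusted p = 0.18 and 0.20). The neutrophil chemokine CXCL1 was the only one of 9 genes in its list to rise, by 0.42 ± 0.32 (adjusted p = 0.0093; 1 adjusted over the list alone), and CXCL3 and CXCL2 were at 0.68 ± 1.0 and 0.66 ± 0.80 (adjusted p = 0.082 and 0.083). Among 7 chemokines for T cells and monocytes, CCL5 (0.56 ± 0.33, adjusted p = 0.0023) and CCL2 (0.52 ± 0.78, adjusted p = 0.040) rose and CXCL10 (0.38 ± 0.60, adjusted p = 0.13) did not pass (2 rose adjusted over the list alone; list adjusted p = 0.46). IL6 (0.76 ± 1.3), IL1B (0.33 ± 0.32), CXCL8 (0.37 ± 0.40) and CD274 (0.33 ± 0.47) did not pass, with adjusted p = 0.13, 0.072, 0.077 and 0.17. Without the animal block, where p values are too small, IL1B and CXCL8 passed (adjusted p = 0.039 and 0.043). With all arrays entered singly IL1B, CXCL8 and IL6 did (adjusted p = 0.030, 0.042 and 0.049). That fit gives all probe sets 1 correlation between technical replicates, 0.21. Its p values can be too small for genes that vary widely between animals, as these did. With animal 1 left out, 1 of the 17 NF-kB genes rose, with animal 6, 7 or 8 left out 2 did, and without animals 1 and 2, a choice made after the data had been seen, 1 did. The arms of animals 1 and 2 lay apart at 6 h along the change of mock slices with time, in which NF-kB genes also rose. Whether this gap adds to their NF-kB differences was not tested.

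Of 15 genes of cell death and inflammasomes, 6 rose and 0 fell at 6 h (6 and 1 adjusted over the list alone; list adjusted p = 0.20), among them PMAIP1, the death receptor FAS, 0.36 ± 0.20, and the kinase RIPK2, 0.30 ± 0.24. Among markers of the thin alveolar type I cells that line the air spaces, 3 of 11 fell and 0 rose (4 and 0 adjusted over the list alone, median −0.14, adjusted p = 0.079). These were the basement membrane collagens COL4A3, −0.39 ± 0.34 (adjusted p = 0.0060), and COL4A4, −0.33 ± 0.37 (adjusted p = 0.046), and EMP2, −0.27 ± 0.14 (adjusted p = 0.0013). In total 3306 probe sets (22.5%) differed at 6 h, 1741 higher and 1565 lower, and 4 differed by 2-fold or more. The share that was higher, 52.7%, was 46.7% with array medians subtracted and 48.8% with quantile normalization.

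At 24 h the antiviral rises were larger. IFIT2 rose by 1.75 ± 0.72 (3.36-fold; adjusted p = 8.1e-11), ISG15 by 1.51 ± 0.58 (2.84-fold; adjusted p = 2e-10) and HERC5, the ligase that attaches ISG15 to proteins, by 1.19 ± 0.55 (adjusted p = 3.5e-10). IFIT3 rose by 1.12 ± 0.43, IFI44 by 1.10 ± 0.75, OASL, a relative of the antiviral oligoadenylate synthetases, by 0.97 ± 0.35, and the RNA sensor IFIH1 by 0.92 ± 0.59. PARP14 (0.70), PMAIP1 (0.63) and IFI44L (0.62) completed the 10 largest rises, each in 9 of 9 animals. The largest falls were FN1, −0.83 ± 0.26 (adjusted p = 1.6e-08), the myosin MYO10, −0.38, IKBIP, −0.35, the basement membrane collagen COL4A2, −0.34, and the transcription factor CUX1, −0.33.

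**Figure D1:**
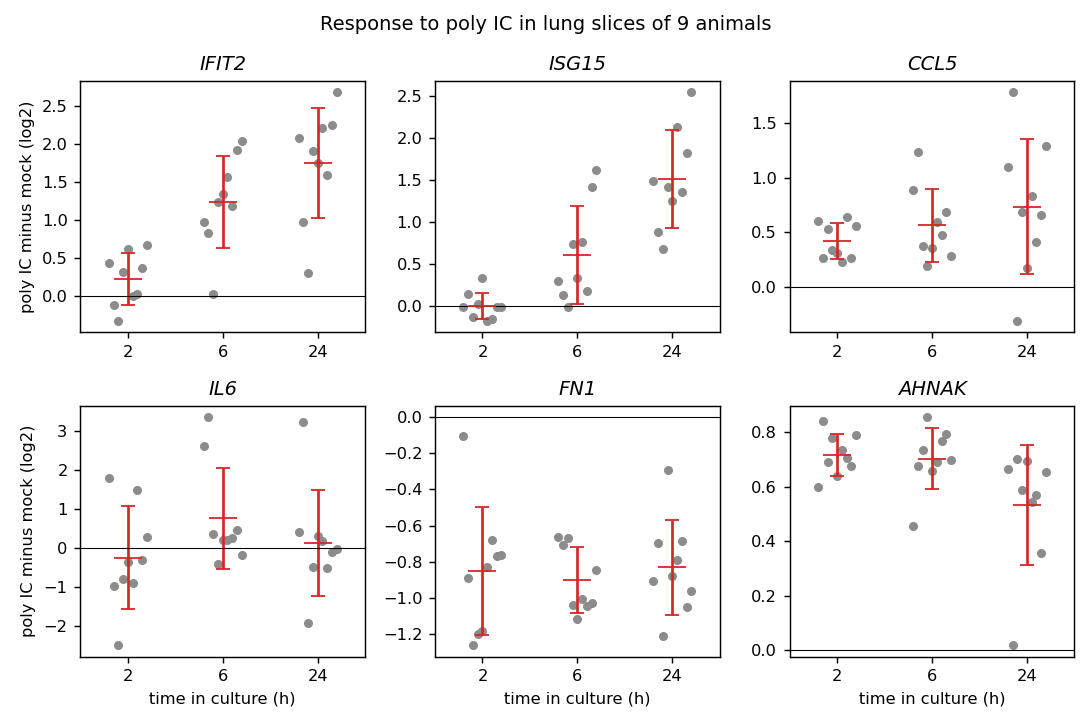
Poly IC minus mock difference (log2) of 6 genes at 2, 6 and 24 h in culture, each panel on its own scale. Grey points are the 9 animals and red bars the mean ± SD; IFIT2 and ISG15 reached means of 1.75 and 1.51 at 24 h, FN1 lay below 0 in every animal at every time, and IL6 spread over several log2 units.

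Of the 37 antiviral interferon-stimulated genes, 31 rose and 0 fell at 24 h (33 and 0 adjusted over the list alone, median 0.33). The list passed with both settings (adjusted p = 8.1e-27, and adjusted p = 0.021 with an estimated correlation). IFIT1 rose by 0.96 ± 0.80 (adjusted p = 1.1e-05, 8 of 9 animals). Of the 18 genes of double-stranded RNA sensing and interferon signalling, 5 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.056), among them IFIH1, the interferon signalling factor IRF9, 0.59 ± 0.34, and RIGI, 0.55 ± 0.30. That list also passed with both settings (adjusted p = 0.0016, and adjusted p = 0.021 with an estimated correlation), but not without the dimmest 30% of genes (adjusted p = 0.056). The MHC class I list was called at the preset correlation (10 of 17 rose and 0 fell; 10 and 1 adjusted over the list alone, median 0.17, adjusted p = 1.5e-05, and adjusted p = 0.61 with an estimated correlation). HLA-F, the immunoproteasome subunit PSMB8 and HLA-C rose by 0.37, 0.31 and 0.29, and 5 of the 12 members outside the HLA genes rose (median 0.12).

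The chemokines CCL5 and CXCL10 rose by 0.74 ± 0.62 (adjusted p = 0.00015, 8 of 9 animals) and 0.52 ± 0.69 (adjusted p = 0.041, 6 of 9) at 24 h, the 2 that rose of 7 in their list (2 adjusted over the list alone; list adjusted p = 0.53). In the list of guanylate-binding and interferon-gamma-type genes, 2 of 7 rose (2 adjusted over the list alone; list adjusted p = 0.24), IDO1, which breaks down tryptophan, by 0.47 ± 0.46 and GBP2 by 0.40 ± 0.18. IL6 (0.13 ± 1.4), IL1B (0.10 ± 0.32), CXCL8 (0.33 ± 0.54) and CD274 (0.34 ± 0.80) did not pass, with adjusted p = 0.86, 0.65, 0.13 and 0.17. Of the NF-kB genes 3 of 17 rose (3 adjusted over the list alone, median 0.12, list adjusted p = 0.46), with NFKB1 itself at 0.35 ± 0.50 (adjusted p = 0.031). Only 1 rose with animal 2, 5, 6 or 8 left out. In the cell death list 5 of 15 rose (5 adjusted over the list alone; list adjusted p = 0.22), and RIPK2 was among them at 0.39 ± 0.43. The endothelial markers CLDN5, −0.27 ± 0.28, and ESAM, −0.23 ± 0.27, both found at junctions between cells, fell (2 of 14; 2 adjusted over the list alone; list adjusted p = 0.96). For the 12 alveolar type II markers the median was 0.027 and the mean 0.022, while the list test pointed down and did not pass (adjusted p = 0.99). At 24 h 2751 probe sets (18.7%) differed, 1500 higher and 1251 lower, all 7 that differed by 2-fold or more being higher. In a fit of only the groups compared the count at 24 h was 1168, while that at 2 h went from 3162 to 5004. The main fit draws 1 estimate of spread per probe set from all 3 times. Its p values at 24 h may therefore be too small for genes whose animals varied more then. Whether CXCL10 and NFKB1 pass in the fit of only the groups compared is not given here.

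Many differences were shared by the 3 times. Altogether 1525 probe sets, 48.2% of those called at 2 h, were called at all 3 times in the same direction, 962 higher and 563 lower, and their median absolute difference was 0.23 at 2 h, 0.23 at 6 h and 0.21 at 24 h. Between 2 and 6 h 2182 calls were shared in direction, against 362 if the calls were independent, and between 2 and 24 h 1793 against 304.9. AHNAK (0.72, 0.70 and 0.53) and FN1 (−0.85, −0.90 and −0.83) were among them. Only 1 of the 1525, a probe set of IFIT3 (0.29, 0.87 and 1.12), had a called difference between the effects at 24 and 2 h. Where 2 probe sets of a gene were both called, 18.9%, 23.3% and 16.3% of the pairs went in opposite directions at 2, 6 and 24 h. For mock slices the share was 4.15% from 2 to 6 h, 13.3% from 6 to 24 h and 17.6% from 2 to 24 h.

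The test of the difference between times asked which poly IC effects grew or shrank. From 2 to 24 h the effect grew for IFIT2 by 1.52 ± 0.50 (adjusted p = 6e-05), ISG15 by 1.51 ± 0.64 (adjusted p = 1.2e-05), HERC5 by 1.20 ± 0.59 (adjusted p = 1.4e-05), OASL by 0.98 ± 0.47 (adjusted p = 3.4e-06) and IFIT3 by 0.83 ± 0.42 (adjusted p = 0.00035), each in 9 of 9 animals. In all 17 probe sets had a called difference, 16 with a larger and 1 with a smaller value at 24 h. Of the 37 antiviral genes the effect grew for 9 (26 adjusted over the list alone, median 0.28), and of the 18 RNA sensing genes for 3 (5 adjusted over the list alone, median 0.057). List tests on differences between times were chosen after the data had been seen, and both lists passed them (adjusted p = 6.2e-57 and 3.4e-08; adjusted p = 7.8e-05 and 5.3e-05 with an estimated correlation). From 2 to 6 h 2 probe sets were called, of OASL (0.97 ± 0.52) and IFIT2 (0.56 ± 0.20), named here after their values were seen. From 6 to 24 h limma called 0, and 1 without animal 1 or animal 2. An unadjusted p under 0.05 was found for 733 probe sets, about the share that a comparison without any effect would give. The count of 17 was 10 without animal 4, and 11 without animal 6, 8 or 9. The count of 2 was 0 when any of animals 1, 2, 4, 6, 7, 8 and 9 was left out and 5 without animal 3.

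From 2 to 24 h more probe sets changed in mock slices than differed between poly IC and mock slices at any of the 3 times. Over 24 h, INHBA, a subunit of the signalling protein activin, rose 16.1-fold (4.01 ± 0.55, adjusted p = 1.7e-19), the stromal protein LRRC15 rose by 3.67 ± 1.5, the matrix protein THBS2 by 3.17 ± 0.98, the cytochrome CYP1B1 by 2.93 ± 0.88 and THAP2 by 2.80 ± 1.0. The growth factor receptor FGFR2 fell most, −2.71 ± 0.39, followed by the carboxypeptidase CPVL, −2.58 ± 0.27, the hedgehog inhibitor HHIP, −2.58 ± 0.53, the hyaluronan synthase HAS3, −2.35 ± 0.51, and ATP8A1, −2.31 ± 0.31. All had the same direction in 9 of 9 animals. From 2 to 24 h 10321 probe sets (70.2%) differed, 4406 higher and 5915 lower, and 532 by 2-fold or more. The share that was higher, 42.7%, was 49.7% with array medians subtracted. List tests on mock slices were chosen after the data had been seen.

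Markers of several lung cell types fell in mock slices over 24 h. All 12 alveolar type II markers fell (12 adjusted over the list alone, median −1.1, adjusted p = 1.5e-05, and adjusted p = 0.50 with an estimated correlation). They included LRRK2, −1.82 ± 0.34, the surfactant protein SFTPD, −1.44 ± 0.61, and SFTA3, −1.31 ± 0.50. Of 11 alveolar type I markers 9 fell and 1 rose (9 and 1 adjusted over the list alone, median −0.53, adjusted p = 0.0074, and adjusted p = 0.51 with an estimated correlation), with COL4A4 at −1.32 ± 0.39 and the water channel AQP4 at −1.20 ± 0.36. Of 14 endothelial markers 12 fell and 1 rose (12 and 1 adjusted over the list alone, median −0.59, adjusted p = 0.015, and adjusted p = 0.63 with an estimated correlation), with RAMP2 at −1.03 ± 0.49. All 10 genes of MHC class II presentation fell (10 adjusted over the list alone, median −1, adjusted p = 5.3e-05, and adjusted p = 0.50 with an estimated correlation), with HLA-DPA1 at −1.46 ± 0.36. Of the MHC class I list 14 of 17 fell and 0 rose (14 and 0 adjusted over the list alone, median −0.24, adjusted p = 0.0095, and adjusted p = 0.51 with an estimated correlation). The antiviral list fell too, with 25 of 37 lower and 2 higher (25 and 2 adjusted over the list alone, median −0.34, adjusted p = 0.0095, and adjusted p = 0.63 with an estimated correlation). IFI27 was at −1.05 ± 0.42 and SAMD9L at −0.95 ± 0.33, while ISG20 rose by 1.23 ± 0.66.

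Genes of hypoxia, stress and inflammation rose in the same slices. All 15 hypoxia and glycolysis genes rose (15 adjusted over the list alone, median 0.98, adjusted p = 1.2e-06, and adjusted p = 0.50 with an estimated correlation), with the glucose transporters SLC2A3 and SLC2A1 at 2.23 ± 0.85 and 1.89 ± 0.97. Of 17 NF-kB genes 14 rose and 0 fell (14 and 0 adjusted over the list alone, median 0.70, adjusted p = 0.00015, and adjusted p = 0.51 with an estimated correlation), with PTGS2, the inducible cyclooxygenase, at 2.61 ± 1.4 and IER3 at 2.05 ± 0.80. Of 9 neutrophil chemokines and growth factors 7 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.99, adjusted p = 0.011, and adjusted p = 0.50 with an estimated correlation), with CXCL8 at 1.5 ± 0.54 and CSF3 at 1.17 ± 0.62. Of 11 genes of the unfolded protein and integrated stress responses 10 rose (10 adjusted over the list alone, median 0.48, adjusted p = 0.00017, and adjusted p = 0.50 with an estimated correlation), and of 10 heat shock genes 9 (9 adjusted over the list alone, median 0.52, adjusted p = 0.012, and adjusted p = 0.61 with an estimated correlation). Of 15 matrix proteases and inhibitors 10 rose and 3 fell (10 and 3 adjusted over the list alone, median 0.58, adjusted p = 0.0031, and adjusted p = 0.50 with an estimated correlation), with the plasminogen activator PLAT at 2.79 ± 0.82 and TIMP1 at 2.52 ± 0.90. In the cell death list 8 of 15 rose and 2 fell (8 and 2 adjusted over the list alone, median 0.21, adjusted p = 0.016, and adjusted p = 0.50 with an estimated correlation).

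**Figure D2:**
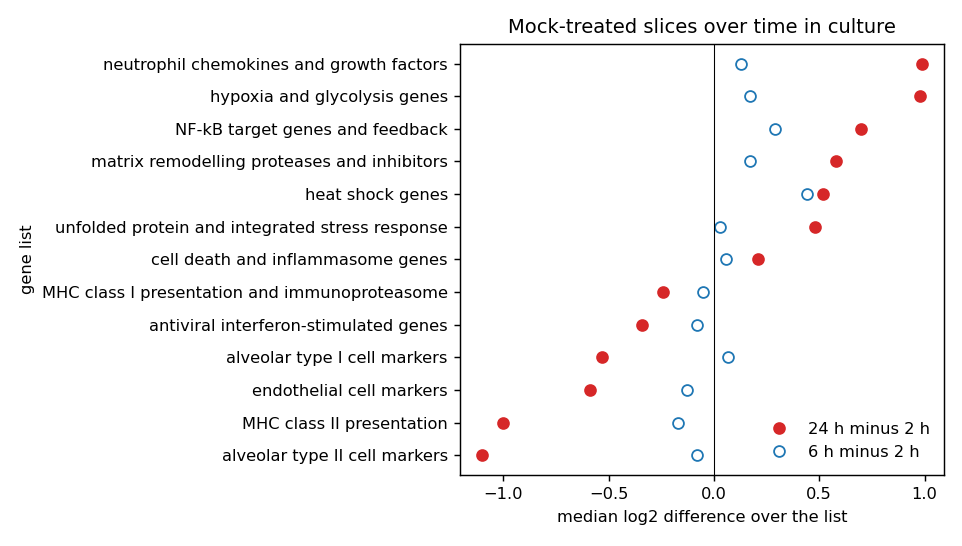
Median log2 difference over each gene list in mock slices, for the 13 lists called between 2 and 24 h. Filled points are 24 h minus 2 h and open points 6 h minus 2 h; alveolar type II markers had the lowest median at 24 h (−1.1) and neutrophil chemokines the highest (0.99).

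Much of the change of mock slices came after 6 h. From 2 to 6 h 2167 probe sets differed, 763 higher and 1404 lower, and from 6 to 24 h 8967 did, 3961 higher and 5006 lower. By 6 h INHBA had risen by 2.04 ± 0.68, COXFA4L3 by 1.38 ± 0.34, LRRC15 by 1.29 ± 0.82, and the hypoxia genes HILPDA and SLC2A3 by 1.22 ± 0.66 and 1.22 ± 0.54. The fractalkine receptor CX3CR1, a marker of monocytes, fell most, −1.07 ± 0.42, with the immediate-early gene FOSB at −1.05 ± 0.58, CPVL at −0.67 ± 0.25, GUSBP11 at −0.64 ± 0.64 and the leukocyte actin regulator CORO1A at −0.62 ± 0.16. From 6 to 24 h the largest rises were those of THBS2 (2.45 ± 0.76), LRRC15 (2.37 ± 0.90), CYP1B1 (2.35 ± 0.86), the reductase AKR1B10 (2.26 ± 0.88) and INHBA (1.97 ± 0.56). The largest falls were HHIP (−2.39 ± 0.42), FGFR2 (−2.25 ± 0.21), the mucin MUC1 (−2.0 ± 0.58), ATP8A1 (−1.95 ± 0.22) and complement C5 (−1.93 ± 0.68). The count from 2 to 6 h was 1134 without animal 8 and 1345 without animal 5, and the share that was higher, 35.2%, was 46.4% with array medians subtracted. From 6 to 24 h it was 44.2%, and 50.2% with array medians subtracted.

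The last comparisons asked how the response differed between animals. Averaged over the 37 antiviral genes, the poly IC response was 0.071 ± 0.060 at 2 h (SD, n = 9; exact sign-flip p = 0.016, adjusted p = 0.047; higher in 7 of 9 animals). It was 0.23 ± 0.098 at 6 h and 0.50 ± 0.26 at 24 h, higher in 9 of 9 animals at both times, with an exact p of 0.0039, the smallest this test can give (adjusted p = 0.018). At 24 h the lowest response was that of animal 2, 0.12, and the highest that of animal 9, 1.00. The inflammatory cytokines, at 0.042 ± 0.27, 0.19 ± 0.33 and 0.14 ± 0.34, did not pass the exact test at any of the 3 times (p = 0.67, 0.14 and 0.27; adjusted p = 0.67, 0.25 and 0.34; higher in 5, 6 and 6 of 9 animals). Nor did the NF-kB genes, at −0.065 ± 0.29, 0.25 ± 0.44 and 0.18 ± 0.44 (exact p = 0.52, 0.12 and 0.25; adjusted p = 0.58, 0.25 and 0.34; higher in 2, 7 and 6 of 9 animals). With 1 animal left out, the cytokine means ran from −0.0076 (without animal 1) to 0.099 (without animal 3) at 2 h, and were 0.11 at 6 h and 0.046 at 24 h without animal 2. Those of the NF-kB genes ran from −0.13 (without animal 1) to −0.026 (without animal 3) at 2 h, and were 0.13 at 6 h without animal 1 and 0.052 at 24 h without animal 2. With only technical replicate 3, the antiviral response at 6 h was 0.19 and did not pass (exact adjusted p = 0.056), and the NF-kB response at 24 h was 0.36 and did (exact adjusted p = 0.012). The antiviral response at 2 h did not pass with any of animals 2 and 4 to 9 left out (highest adjusted p = 0.094 by the exact test), nor with array medians subtracted (0.042; adjusted p = 0.19) or quantile normalization (0.048; adjusted p = 0.18). It also failed as a median over the list (exact adjusted p = 0.082) and with only technical replicate 1 or 2 (exact adjusted p = 0.18 and 0.55).

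**Figure D3:**
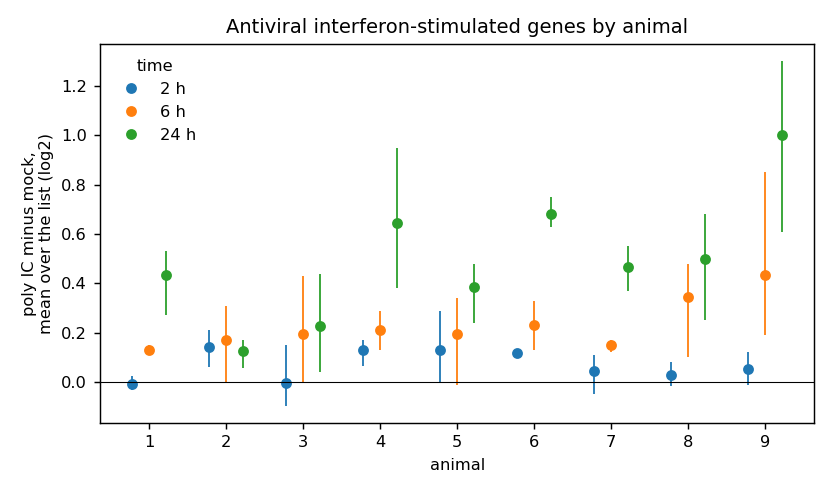
Mean poly IC minus mock difference (log2) over the 37 antiviral interferon-stimulated genes for each of the 9 animals, at 2, 6 and 24 h. Points are the mean of the 3 technical replicates and lines their range; at 24 h the animals ran from 0.12 (animal 2) to 1.00 (animal 9).

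Responses of the 9 animals at different times were related in 9 tests. For the inflammatory cytokines the responses at 6 and 24 h had r = 0.87 (exact permutation p = 0.0015, adjusted p = 0.013) and rho = 0.78 (exact p = 0.017, adjusted p = 0.11). Without animals 1 and 2, the farthest from the median at 6 h, r was 0.58, so the relation rests in part on these 2 together. The arms of these 2 animals also lay apart at 6 h along the change of mock slices with time, by 0.26 and 0.27. Whether this gap underlies the relation was not tested. The relation did not pass with only animal 1 (r = 0.92, exact adjusted p = 0.067) or only animal 2 left out (r = 0.78, exact adjusted p = 0.12). Nor did it with only technical replicate 1 (r = 0.15, exact adjusted p = 0.79) or 2 (r = 0.68, exact adjusted p = 0.20), or with medians over the list (r = 0.77, exact adjusted p = 0.15). For the antiviral genes at 6 and 24 h r was 0.71 (exact p = 0.034, adjusted p = 0.13), rho 0.68 (exact p = 0.050, adjusted p = 0.15), and r 0.43 without animals 8 and 9. For the NF-kB genes r was 0.66 between 2 and 6 h (exact p = 0.044, adjusted p = 0.13; rho 0.57, exact p = 0.12, adjusted p = 0.27; r 0.18 without animals 1 and 7) and 0.64 between 6 and 24 h (exact p = 0.087, adjusted p = 0.20; rho 0.75, exact p = 0.025, adjusted p = 0.11; r 0.51 without animals 1 and 2). With 1 animal left out, r fell to 0.335 for the antiviral genes at 6 and 24 h (without animal 9). It fell to 0.241 for the NF-kB genes at 2 and 6 h (without animal 1). The other 5 relations had r between −0.079 and 0.25 (exact adjusted p of 0.93 or above). The labels used here give no array batch, so relations within batches were not computed.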

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

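The list tests on differences between times, the splits, the correlation between probe sets of a gene, the batch labels, the hypoxia and endothelial values of animal 2, the place of each of its arms on the axis, the 6 h values of animals 1 and 2, and the tests on exchanged arms, single arrays and the interferon response of animal 2 were chosen only after the result was seen.

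The poly IC effect differed between 24 and 2 h, by limma's test of the difference, for 17 probe sets. The differences of OASL were 1.64 and 0.98 for its 2 probe sets, those of IFIT2 1.52 and 0.77, and those of IFIT3 0.95 and 0.83. ISG15 was at 1.51, HERC5 at 1.20, IFI44 at 0.89, IFIH1 at 0.82, IFI44L at 0.72 and RIGI at 0.55. IRF9 was at 0.54, IFI6 at 0.50, TRIM14 at 0.50 and GBP2 at 0.39. A probe set without a gene name in the probe table was at −0.42. Between 6 and 2 h, OASL differed by 0.97 and IFIT2 by 0.56.

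Gene lists whose poly IC effect differed between times by camera at the preset correlation are given by their median difference over the list. Between 6 and 2 h these were antiviral interferon-stimulated genes (0.065), double-stranded RNA sensing (0.036), chemokines for mononuclear cells (0.16), neutrophil chemokines (0.29), NF-kB targets (0.26), cell death (0.041), immediate-early genes (0.36), heat shock (0.15), matrix remodelling (0.13), alveolar type I markers (−0.13) and B cell markers (0.12). None of these 11 passed with an estimated correlation in camera (0 of 36 lists). Between 24 and 6 h they were antiviral genes (0.24), double-stranded RNA sensing (0.042), immediate-early genes (−0.22) and alveolar type I markers (0.14). Between 24 and 2 h they were antiviral genes (0.28), double-stranded RNA sensing (0.057), mononuclear chemokines (0.09), neutrophil chemokines (0.27), NF-kB targets (0.17), fibroblast markers (0.13) and B cell markers (0.098). At both of these steps, antiviral genes and double-stranded RNA sensing were the 2 lists that also passed with an estimated correlation.

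In 12 of 117 sets of 9 values, 1 animal stood far from the others, where chance gives about 1 in 20 sets such a value (5%). Animal 1 stood apart for DNAJA4 at 2 h (1.76, others 0.043 to 0.91), FN1 at 2 h (−0.11, others −1.26 to −0.68) and AHNAK at 6 h (0.46, others 0.66 to 0.86). Animal 2 stood apart for IL6 at 24 h (3.23, others −1.92 to 0.42), for the NF-kB response at 24 h (1.24, others −0.31 to 0.37), and, in mock slices from 6 to 24 h, for THBS2 (0.69, others 2.22 to 3.35) and LRRC15 (0.20, others 2.12 to 3.36). Animal 4 had a low UBR4 at 6 h (0.21, others 0.53 to 0.84). Animal 9 stood apart for IGFBP7 at 2 h (1.06, others 0.43 to 0.71), IFIT1 at 6 h (1.44, others 0.24 to 0.71), IFIT1 at 24 h (2.76, others −0.24 to 1.25) and IFI44L at 24 h (1.80, others 0.12 to 0.79).

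Exchanging the labels of the compared slices within animals, in 100 splits drawn at random with the real one included, tested whether chance could give such counts. For the effects between times no slices were relabelled. There the poly IC minus mock differences of the 2 times were exchanged within an animal. For poly IC against mock only 1 split, the real one, gave as many at 2 h (3162, highest other 1531), at 6 h (3306, highest other 1438) and at 24 h (2751, highest other 2190). The same held, with 1 split each, for the effect at 6 against 2 h (2, highest other 1) and 24 against 2 h (17, highest other 9), and for mock slices at 6 against 2 h (2167, highest other 80), 24 against 6 h (8967, highest other 6482) and 24 against 2 h (10321, highest other 8373). Chance was unlikely, though not excluded, at this number of splits for these 8 counts. For the effect at 6 against 2 h this rests on 2 calls against 1, and leaving out animal 1 alone gave 0 calls. For the effect at 24 against 6 h the real count by limma was 0 (733 at an unadjusted p under 0.05, about the share without any effect). All 100 splits therefore had to give as many and say nothing about chance (highest other 0).

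Altogether 1525 probe sets were called in 1 direction at all 3 times, with a median absolute difference of 0.23 at 2 h, 0.23 at 6 h and 0.21 at 24 h. If a tissue response complete by 2 h were the whole cause, different probe sets of a gene should follow each other as in the mock change from 2 to 6 h, where their correlation across 2037 genes, divided by its reliability, was 0.73 (95% interval 0.69 to 0.78). For the mean poly IC effect it was 0.32, with an upper end of 0.38, and at 2, 6 and 24 h alone 0.32, 0.39 and 0.56 (0.46 to 0.64 at 24 h), all below the mock interval, which argues against that explanation as the whole cause, least so at 24 h. The value of 0.32 is in line with a part of the signal being tied to single probe sets on the poly IC arrays. Arrays of the arms handled in different batches cannot be told apart from treatment, because 0 arrays have a batch label.

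The arms of animals 1 and 2 lay apart along the axis of the mock change with time, by 0.26 for animal 1 and 0.27 for animal 2 at 6 h (other 7 animals −0.15 to 0.033) and by 0.47 for animal 2 at 24 h (others −0.22 to 0.088). Exchanged arm labels would turn the correlation of an animal with the mean of the other 7 animals negative. At 6 h it was 0.19 for animal 1 and 0.39 for animal 2 across probe sets, which are not independent (each of the 7 with the rest 0.47 to 0.74). This argues against exchanged array labels, but not against exchanged slices, since part of the signal may be tied to the arrays. For animal 2 at 24 h that correlation was −0.19 (others 0.24 to 0.62), as an exchange would give, but the antiviral mean, a test chosen after that value was seen, was above 0 in each technical replicate (lowest 0.057) as in the other 8 animals, which an exchange forbids. All technical replicates lay above the means of the other 7 animals in 3 of 3 pairs. Single replicates overlapped: at 6 h the lowest were 0.17 (animal 1) and 0.21 (animal 2), and animal 5 reached 0.30. At 24 h the lowest of animal 2 was 0.19 and animal 1 reached 0.23. A single failed array was therefore not excluded. At 24 h the mock slices of animal 2 stood at 0.196 on the axis (other 8 animals 0.469 to 0.729) and its poly IC slices at 0.662 (others 0.295 to 0.61). The gap therefore includes a lag of its mock slices. A uniform advance of its poly IC slices over its mock slices would lower the alveolar type II markers, but their median was 0.31 (others −0.34 to 0.11). Its hypoxia median of 1.1 (others −0.51 to 0.19) and endothelial median of −0.71 (others −0.28 to 0.27) went the way of that change. Its antiviral mean of 0.12, the lowest of 9 animals, gave no sign of a larger interferon response. It does not exclude one, since antiviral genes fell with culture time in mock slices (median −0.34), which may lower this mean. At 6 h the antiviral means were 0.13 for animal 1, the lowest, and 0.17 for animal 2, and culture change was left undecided there, since animal 2 had the lowest type II and type I medians (−0.42 and −0.38) but hypoxia and endothelial medians of 0.04 and 0.12 inside the range of the others, as were the type II and hypoxia medians of animal 1 (−0.079 and 0.055), and a difference between the pieces of lung taken was not tested.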

How the results depend on the processing

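The fits with 27 set terms, without animals 1 and 2, and with the mean of a gene's probe sets for the counts were chosen after seeing the data. Of 365 values of named genes under alternatives, 352 kept their side of the threshold, 4 were weaker, 7 stronger and 2 reversed. Over all results, responses and relations included, the sign changed for 29 values that passed no threshold under either setting. AHNAK reversed with the mean of its probe sets, to −0.072 at 2 h and −0.098 at 6 h, since its probe sets differ in sign. Where no cause is named, the cause was not tested. Signal over background was not given for these arrays, so its limit on low values is unknown.

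Counts of the poly IC effect between times (6 against 2 h, 24 against 6 h, 24 against 2 h) moved under several settings. With no replicate block, so without the animal as a block, they were 5, 2 and 31, but p values are too small in that fit, since animal levels had already been removed. The counts were 6, 6 and 27 with all arrays entered singly, 6, 6 and 27 with 27 sets as fixed terms, 0, 1 and 8 without the dimmest 30% of probe sets, and 0, 4 and 35 without animals 1 and 2. Both fits of single arrays give all probe sets 1 correlation between technical replicates, so some of their p values can be too small. The median of technical replicates gave 1 for 24 against 6 h. Leaving out each animal gave 0 to 5, 0 to 1 and 10 to 24. These counts of 0 are limma's. In the fit of all animals, 373 probe sets for 6 against 2 h and 733 for 24 against 6 h had an unadjusted p under 0.05. The 733 are about the share that no effect would give, and the 373 are fewer.

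With a single technical replicate, and so fewer arrays, poly IC against mock at 2, 6 and 24 h gave fewer, 1359, 1523 and 1161 with replicate 1, 784, 1104 and 477 with replicate 2, and 1561, 908 and 1577 with replicate 3. The effect at 6 against 2 h gave 0 with each, that at 24 against 6 h 1 with replicate 1, and that at 24 against 2 h 11 with replicate 2 and 3 with replicate 3. Mock slices at 6 against 2 h gave 60, 1153 and 392, and at 24 against 6 h 5062 with replicate 2. With only the groups compared, poly IC gave 5004 at 2 h and 1168 at 24 h, and the effect 4 at 6 against 2 h and 9 at 24 against 2 h.

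With 1 probe set per gene, which tests fewer, poly IC gave 1933, 1990 and 1695, the effect 0 at 6 against 2 h and 1 at 24 against 6 h, and mock slices 1378, 5607 and 6423. With the mean of a gene's probe sets these were 1794, 1813 and 1527, 1 at 24 against 6 h, and 1279, 5625 and 6400. At least 2-fold differences numbered 3, 4 and 7 for poly IC, 0 and 4 for the effect at 6 and 24 against 2 h, and 29, 266 and 532 for mock slices. At an adjusted p under 0.01 there were 1926, 2049 and 1523 for poly IC, 0 and 11 for the effect at 6 and 24 against 2 h, and 861 for mock slices at 6 against 2 h. Leaving out each animal gave 1134 to 2665 for mock slices at 6 against 2 h.

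Gene lists called fell to 0 at 2 h and 0 at 6 h with an estimated correlation in limma's camera, and were 6 at 6 h and 6 at 24 h with fry. Without animals 1 and 2 there were 2 at 2 h, and leaving out each animal gave 1 to 3 at 2 h and 2 to 4 at 6 h. The antiviral response at 2 h no longer passed as a median over the list (0.0552, exact adjusted p = 0.082). Nor did it with technical replicate 1 (0.0676, exact adjusted p = 0.18) or 2 (0.043, exact adjusted p = 0.55). It was 0.0424 with array medians subtracted, 0.0483 with quantile normalization and 0.062 to 0.0808 leaving out each animal. With technical replicate 3 the antiviral response at 6 h was 0.187 and no longer passed (exact adjusted p = 0.056), and the NF-kB response at 24 h was 0.364 and passed (exact adjusted p = 0.012). The cytokine relation between 6 and 24 h no longer passed at 0.768 with medians over the list, 0.148 and 0.675 with technical replicates 1 and 2. Leaving out each animal gave 0.784 to 0.924, and it no longer passed without animal 1 or animal 2. With technical replicate 3, relations passed for antiviral genes at 6 and 24 h (0.915), cytokines at 2 and 6 h (0.795) and NF-kB genes at 2 and 6 h (0.825).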

Other observations

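The list tests on mock slices and the comparison of arms over time were chosen only after the result was seen. Antiviral genes fell in mock slices over 24 h, while in poly IC slices about as many rose as fell. Of the 37 antiviral genes, 25 fell and 2 rose in mock slices from 2 to 24 h (median −0.34), whereas in poly IC slices 11 fell and 10 rose (median −0.007). IFIT1, which binds viral RNA, went from a mean of 6.99 at 2 h to 6.31 at 24 h in mock slices and from 7.38 to 7.27 in poly IC slices. ISG15 went from 5.34 to 5.19 in mock slices and from 5.34 to 6.69 in poly IC slices.

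Stress and feedback genes had already moved in mock slices from 2 to 6 h. Of 10 heat shock genes 4 rose and 0 fell (9 and 0 adjusted over the list alone, median 0.44, adjusted p = 4.1e-06, and adjusted p = 0.50 with an estimated correlation), among them the small heat shock protein CRYAB at 0.68 and the co-chaperone BAG3 at 0.65. Of 13 feedback inhibitors of cytokine signalling 5 rose and 0 fell (5 and 0 adjusted over the list alone, median 0.17, adjusted p = 0.00024, and adjusted p = 0.50 with an estimated correlation), among them CD274, the ligand of PD-1, at 0.76 and the decoy receptor IL1R2 at 0.76. Of 7 epithelial alarmins and type 2 genes 3 rose and 0 fell (3 and 0 adjusted over the list alone, median 0.35, adjusted p = 0.0031, and adjusted p = 0.35 with an estimated correlation), with TSLP at 0.79. Markers of mast cells and macrophages fell from 2 to 24 h without their lists passing: 4 of 4 mast cell markers (4 adjusted over the list alone, median −0.74, adjusted p = 0.11), with CPA3 at −2.10, and 10 of 13 macrophage markers, with 1 higher (10 and 1 adjusted over the list alone, median −0.56, adjusted p = 0.11), with CD14 at −1.07.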
